A study of Mus musculus with 12 samples.

How the data were processed

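RNA was sequenced from sorted mouse pro-B cells (CD19+ B220+ CD43+, bone marrow) and DN3 thymocytes (Lin- CD25+ CD117-, thymus), per the labels. Controls carried Cdkn2a-/- Il7ra-cre/+, and the other genotype, called DKO here, carried Cdkn2a-/- Ezh2fl/fl Il7ra-cre/+. Each of the 4 groups had 3 samples, 12 libraries in all. The labels call the samples independent without saying whether each came from its own animal, so p-values of the genotype and interaction fits measure the spread between these samples. Those of Fisher's exact tests and of permutations are taken over genes or segments and do not measure that spread. List tests against the other genes rest largely on genes as well. Libraries were made with the Nugen Ovation Ultralow kit, per the labels' protocols, and no strand setting is stated, so reads of a gene and of its antisense partner could not be told apart.

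Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.33, aligned to mm10 with TopHat2 2.1.0, counted per gene with HTSeq 0.6.1 and analysed by the submitters with edgeR. The authors deposited 1 table per cell type, and its values per library behave as RPKM over the whole gene span, introns included. Per the file headers, the same tables hold the authors' log2 fold change and average log2 CPM, their likelihood ratio score, a p-value and an adjusted p-value. They also hold marks for higher and lower genes, which in the values follow the authors' adjusted p-value under 0.01. Genes listed had over 1 CPM in at least 2 libraries of the cell type, as read from the values. The deposited symbols were kept; of the 14324 pro-B genes 366 had none, of which 342 were named from GENCODE M21, and of the 14339 DN3 genes 406 had none, of which 382 were named.

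RPKM times span gave CPM that summed to 1000000 per library, and dividing by the smallest step gave whole reads for 100% of values within a tolerance of 0.01 reads. Recovered depth was 14.2 to 26.0 times 1e6 reads per library over the genes listed. With 3 reads as the floor, a gene with no reads in a library lies under 0.115 to 0.211 CPM; this floor covers counting error only. Fits used limma 3.58.1 in R 4.3.3 with an intensity trend on log2(CPM + 1), after scaling by trimmed means of M values computed on the recovered reads (30% of M and 5% of A trimmed). Fold changes are therefore on the log2(CPM + 1) scale and understate changes of low genes. The planned count models were not used because the deposited unit is RPKM; the planned fallback, log2(value + 1), was applied to CPM, since RPKM over spans with introns puts most long genes far below the pseudocount of 1, and log2(RPKM + 1) was run as an alternative. Genes needed a CPM worth 10 reads at the median depth in at least 3 libraries and 15 reads in all, which removed 34 of 14324 genes in pro-B and 310 of 14339 in DN3. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Values are means ± SD over 3 libraries in scaled CPM, SE belongs to the fitted log2 fold change, and coordinates are mm10 as deposited.

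Pro-B and DN3 were each fitted alone. The genotype by cell type interaction was fitted with limma on all 12 libraries over 13166 genes in both tables; the plan left it out for values normalized apart, and it was run because recovered reads could be scaled jointly. Overlap of calls was tested with a one-sided Fisher's exact test over genes tested in both cell types. The 24 gene lists, the rule for named genes and the first alternatives were set before the data were examined. The rule names Ezh2 and Cdkn2a; per cell type the 10 largest log2 fold changes in each direction among called genes with a mean of at least 1 CPM in the higher group and no overlap of the groups; up to 4 members per list by p; 5 interaction genes per direction by p; and up to 10 genes per direction called in both cell types. Unnamed gene models and antigen receptor V, D and J segments were left out of the rule, and any other gene named was chosen after its values were seen. Lists with at least 3 tested members were tested against the other genes with camera, at a preset correlation of 0.01 and at an estimated correlation. They were also tested with fry, which asks whether a list moves on balance in 1 direction and does not compare it with the other genes. Where many genes change, a list can pass by fry without standing out from the others. Chance puts 10% of genes with 3 against 3 values fully apart, so lack of overlap alone is weak evidence.

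Replicate numbers pair the pro-B samples: deviations from the group means of same-numbered control and DKO libraries correlated at 0.477, 0.248 and 0.289 across genes, all over the bound set for pairing. The labels do not say what a number shares. With the number as a block, pro-B calls were 2532 higher and 2367 lower. Reads show part of what a number shares: the 4 libraries numbered 3 had Xist at 1579 to 5139 CPM and Ddx3y at no more than 0.0621 CPM, while the other 8 had Xist at no more than 6.40 CPM and Ddx3y at 31.9 to 61.5 CPM. By these genes 1 of 3 samples in every group was female, so sex was balanced between genotypes.

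Alternatives were median-of-ratios scaling, no filter, the replicate block, pseudocounts of 0.1 and 5, all 12 libraries with 1 shared spread, an added bound of 1 on the absolute log2 fold change, an estimated correlation for lists, and leaving out each library. Added after the data were seen were no scaling beyond the library total, voom on the recovered reads, log2(RPKM + 1), the log2 share of ribosomal RNA reads as a covariate, a sex term, and DN3 without controls 1 and 2, where the lone control 3 is assumed to vary like the other groups. The list test of the interaction was repeated in these fits except voom. Ribosomal RNA reads were those of 4 listed genes at the ribosomal locus on chromosome 17, which hold near-identical sequence. Mitochondrial ribosomal RNA was not counted among them. The fits were tested on simulated reads with known changes. Of genes with a log2 change of 1, 2, 3 and 4, 33.3%, 81.6%, 94.0% and 96.0% were called in simulated pro-B libraries (14289 genes, 6.79% of calls false), and 14.9%, 54.5%, 62.2% and 91.7% in simulated DN3 libraries (13950 genes, 7.21% false). The simulated interaction (13166 genes) recovered 60.5% of effects of log2 size 2 present in 1 cell type, with 11.0% of 136 calls false. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.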

Results

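The data are gene-level RNA-seq values from 12 libraries: pro-B cells, the early B cell stage that rearranges its heavy chain genes, and DN3 thymocytes, the stage that rearranges T cell receptor beta genes. In each cell type 3 control libraries (Cdkn2a-/- with Il7ra-cre) were set against 3 DKO libraries that also carry floxed Ezh2. Ezh2 is a catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at silenced genes; Cdkn2a encodes the p16Ink4a and p19Arf inhibitors of growth. Depth in units of 1e6 reads was 22.0 ± 3.61 in pro-B controls, 22.1 ± 1.69 in pro-B DKO, 17.6 ± 3.07 in DN3 controls and 19.1 ± 3.84 in DN3 DKO (SD, n = 3 each). Ribosomal RNA took 10.1 ± 2.0% and 9.03 ± 2.32% of pro-B control and DKO reads, and 14.4 ± 7.18% and 4.99 ± 1.91% of DN3 control and DKO reads. DN3 controls 1 and 2 stood apart with 20.2% and 16.6%, and with 722 and 684 genes listed at 0, against 222 in DN3 control 3 and 10, 69 and 80 in DN3 DKO.

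Ezh2 (ENSMUSG00000029687, chromosome 6, 47530274 to 47595341) was read at 653 ± 40.5 CPM in pro-B controls and 491 ± 90.2 CPM in pro-B DKO, a log2 change of -0.43 ± 0.18 (SE) that missed the threshold (limma, adjusted p = 0.113). In DN3 it was 294 ± 89.1 and 288 ± 44.6 CPM (log2 change 0.01 ± 0.24, adjusted p = 0.993). A floxed allele loses only some exons, and reads were counted over the whole gene, so these values check the deletion poorly. Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), deleted in both genotypes per the labels, still gave reads and rose in pro-B DKO from 3.06 ± 0.885 to 42.1 ± 15.2 CPM (log2 change 3.37 ± 0.27, adjusted p = 0.00022). In DN3 controls 1, 2 and 3 it stood at 0, 0.0647 and 0.639 CPM and in DN3 DKO at 2.84, 5.60 and 10.1 CPM (log2 change 2.44 ± 0.50, adjusted p = 0.0298). That DN3 call was lost without DN3 control 1 (adjusted p = 0.0516), control 2 (0.0845), DKO 2 (0.131) or DKO 3 (0.145), with pseudocount 5 (0.0570, log2 change 1.04), with voom (0.180), with the ribosomal RNA covariate (0.717, log2 change 2.39) and without controls 1 and 2 (0.269, log2 change 2.06). The size of the change hardly moved with the covariate. Its neighbour Cdkn2b, a further inhibitor of cyclin-dependent kinases, rose in pro-B DKO from 2.74 ± 0.352 to 15.2 ± 6.42 CPM (log2 change 2.05 ± 0.27, adjusted p = 0.00205). In DN3 it was listed at 0 in every control and at 0.691, 2.16 and 2.55 CPM in DKO, without passing the test (adjusted p = 0.138).

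**Figure D1:**
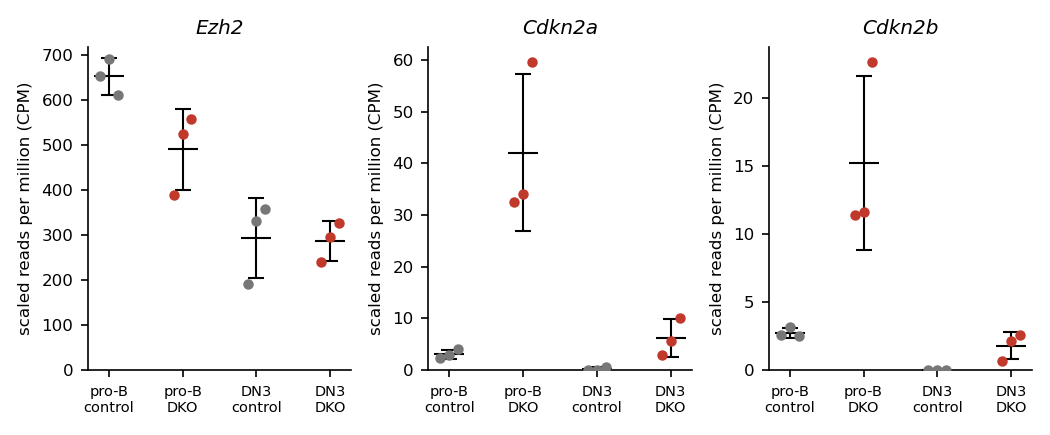
Scaled CPM of Ezh2, Cdkn2a and Cdkn2b in each of the 12 libraries (points), with mean and SD over 3 libraries (bars), by cell type and genotype. Ezh2 reads persist in DKO (491 CPM in pro-B, 288 CPM in DN3), and Cdkn2a is higher in DKO than in controls in both cell types.

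How pro-B cells of the DKO genotype differ from controls was addressed by the comparison of pro-B DKO with pro-B controls, with the loss of Ezh2 itself not checked. Genes that are normally silent or low in B cell precursors rose from near 0: Lin28b, an RNA-binding protein of fetal progenitors, went from 0.218 ± 0.122 to 32.3 ± 8.60 CPM (log2 change 4.75 ± 0.22, adjusted p = 5.8e-05, n = 3 per group). Ptprm, a receptor tyrosine phosphatase, went from 2.96 ± 2.40 to 155 ± 32.2 CPM (log2 change 5.44 ± 0.38), and Tead1, a DNA-binding partner of Yap1, from 1.72 ± 0.783 to 103 ± 23.6 CPM (log2 change 5.26 ± 0.25). The prolactin receptor Prlr rose to 178 ± 63.3 CPM from 4.33 ± 0.656, and the BMP receptor Bmpr1a to 31.0 ± 14.9 CPM from 0.139 ± 0.0605. Bves, Rbfox2, Mpped2, Rbms3 and Atp11a complete the 10 genes named for the largest rises, with log2 changes of 4.77, 4.58, 4.48, 4.41 and 4.41. In all, 1975 genes rose and 1342 fell of 14290 tested, with a median log2 change of 1.17 among those that rose and -0.68 among those that fell. Of the genes that rose, 724 (36.7%) had under 1 CPM in controls, and of those that fell 76 had under 1 CPM in DKO. The deposited tables keep genes over 1 CPM in at least 2 libraries of the cell type, so a gene low in controls is listed mostly through DKO. The filter treats the genotypes alike, but genes low in both were not seen.

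The 10 genes named for the largest falls in pro-B DKO include receptors and membrane proteins of lymphocytes. Il2ra (CD25), which marks the pre-B stage that follows, fell by 1.98 on the log2 scale, from 73.1 ± 34.0 to 17.8 ± 7.71 CPM (SE 0.39, adjusted p = 0.0107). Fcrla, an Fc receptor-like protein of B cells, fell from 165 ± 49.4 to 38.9 ± 16.4 CPM (log2 change -2.10 ± 0.32), and the tetraspanin Tspan2 from 59.9 ± 3.03 to 13.4 ± 0.929 CPM (log2 change -2.09 ± 0.13). Steap4, Capn11, Dpt, Sit1, Klra1, Lmo4 and Als2cl fell with log2 changes of -2.48, -2.18, -2.03, -2.03, -1.99, -1.98 and -1.97. The call of Capn11 was lost without pro-B control 2, DKO 1 or DKO 2, and that of Dpt without control 1, control 2, DKO 2 or DKO 3, with adjusted p of up to 0.156 and 0.0737 over their alternatives. Klra1 belongs to a family of near-identical genes, so its reads are uncertain.

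Developmental regulators that pass the filter of the deposited tables were mostly higher in pro-B DKO. Of 39 Hox genes listed 10 could be tested, and 9 rose and 0 fell (10 adjusted over the list alone; median log2 change 1.85, or 1.90 with genes at 0 in all controls at their bound; camera adjusted p = 1.3e-08). Hoxc4 had 0 reads in all 3 controls and 10.3 ± 1.3 CPM in DKO, at least 216-fold higher against a floor of 3 reads over the group, and Hoxb6 rose from 0.142 ± 0.152 to 9.10 ± 0.467 CPM. Transcription factors of other lineages, which pattern heart, limb, eye and other tissues, had 64 members listed and 10 tested, with 9 higher and 0 lower (9 adjusted over the list alone; median 1.99, or 2.96 at the bound; camera adjusted p = 1.03e-07). Tbx15 rose from 0.133 ± 0.116 to 13.7 ± 6.47 CPM, Isl1 from 0.0346 ± 0.03 to 8.45 ± 2.05 CPM and Foxc1 from 0.101 ± 0.059 to 7.2 ± 1.39 CPM; Six1 had 0 reads in controls and was at least 61.7-fold higher. Multipotent and early thymic progenitor genes had 12 of 19 members higher and 0 lower (12 adjusted over the list alone; median 0.94, camera adjusted p = 7.17e-05). Among them the stem cell factor receptor Kit rose from 20.6 ± 4.56 to 96.0 ± 22.8 CPM (log2 change 2.16 ± 0.21), Meis1 from 15.4 ± 3.80 to 72.6 ± 18.4 CPM and Hlf from 0.272 ± 0.225 to 5.85 ± 2.35 CPM. The fetal lymphopoiesis list had 6 of 10 higher and 1 lower (6 and 1 adjusted over the list alone; median 1.04, or 1.20 at the bound; camera adjusted p = 0.00246). Besides Lin28b, the RNA-binding protein gene Igf2bp3 rose from 62.1 ± 16.3 to 204 ± 36.4 CPM, while Arid3a fell from 64.6 ± 11.1 to 27.7 ± 8.41 CPM. None of these 4 lists passed with an estimated correlation: adjusted p was 0.117 for Hox genes, for transcription factors of other lineages and for progenitor genes and 0.438 for the fetal list; by fry it was 7.51e-05, 0.000264, 7.51e-05 and 0.0022. Members low in both genotypes are not in the tables, so counts, medians and tests of the first 2 lists hold only for members that reached 1 CPM somewhere. Their tested members summed to just 9.38 and 5.74 CPM in controls. Members that low in controls are listed mostly through DKO and have little room to fall, so these tests cannot show that the whole lists rose. Of all 1215 pro-B genes tested with under 1 CPM in controls, 724 were called higher.

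Cell cycle genes moved the other way: 13 of 28 fell and 0 rose (18 lower adjusted over the list alone; median log2 change -0.88, camera adjusted p = 1.58e-08). They include the replicative helicase subunits Mcm2, which fell from 113 ± 11.4 to 52.6 ± 10.2 CPM, Mcm3, from 170 ± 2.33 to 92.2 ± 13.3 CPM, Mcm4 and Mcm7. With an estimated correlation the list lost its call (adjusted p = 0.688), as its members correlated at 0.856, and by fry adjusted p was 0.0582.

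Lymphoid lists were mixed in pro-B DKO, and none of them passed the camera test. By fry, T lineage genes (adjusted p = 0.00408), IL-7 receptor and STAT5 target genes (0.0439) and innate lymphoid regulators (0.04995) passed in the higher direction. The fry test does not compare a list with the other genes. B lineage genes had 3 higher and 4 lower of 27 (camera adjusted p = 0.744): the lineage factor Ebf1 rose from 3075 ± 547 to 7455 ± 2717 CPM and Erg and Enpep rose, while Cd72 fell from 200 ± 18.5 to 58.2 ± 22.3 CPM and Fcrla, Blk and Spib fell. Later B cell stage genes had 0 higher and 3 lower of 18 (Irf4, Il2ra, Spib; adjusted p = 0.0586). That list passed with the replicate block (0.0272), with median-of-ratios scaling (0.0456), without scaling (0.0124), without pro-B control 1 (4.11e-06) and without DKO 2 (0.0352), and in none of these with an estimated correlation (0.353 to 0.854). Irf4, a factor of the pre-B transition, fell from 462 ± 66.2 to 181 ± 55.9 CPM. T lineage genes had 6 higher and 3 lower of 19 (9 and 3 adjusted over the list alone; adjusted p = 0.222): Gata3 rose from 0.232 ± 0.0925 to 2.85 ± 0.517 CPM, Notch3 and Bcl11b rose, and Lck fell. Innate lymphoid regulators had 6 higher and 0 lower of 20 (adjusted p = 0.258), among them Sox13, Rora, which went from 0.92 ± 0.211 to 7.07 ± 3.35 CPM, Ikzf2, Zbtb7b and Zbtb16, the PLZF factor of innate-like lymphocytes, at 0.165 ± 0.139 and 1.74 ± 1.31 CPM. Notch target genes had 1 higher (Notch3) and 1 lower (Il2ra) of 11 (adjusted p = 0.744), and post-beta-selection thymocyte genes 0 of 9 (0.862). IL-7 receptor and STAT5 target genes had 3 higher (Socs3, Stat5b, Cish) and 0 lower of 16 (0.243). With the replicate block further members passed: Dtx1 higher (adjusted p = 0.0294), and Heyl (0.00514), Cd2 (0.0369), Ets2 (0.0314) and Socs1 (0.0387) lower. The calls of Spib (adjusted p = 0.0519), Zbtb7b and Cish were lost without pro-B control 2, that of Zbtb7b also without DKO 2 (at most 0.0865) and that of Cish also without control 1, DKO 1 or DKO 3 (at most 0.151).

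Polycomb, growth control and other lists in pro-B DKO held single called members. Core PRC2 subunits and partners had 1 higher (E130012A19Rik, also called Epop) and 1 lower (Rbbp7) of 11 (camera adjusted p = 0.203). PRC1 subunits had 2 higher and 1 lower of 19 (0.621): Bmi1, which restrains Cdkn2a, rose from 24.7 ± 1.96 to 74.5 ± 9.69 CPM (log2 change 1.55 ± 0.14), Rybp rose and Ring1 fell. CDK inhibitors had 2 higher (Cdkn2b, Cdkn1c) and 1 lower (Cdkn2c) of 7 (0.744), with a median log2 change of -0.40 and a mean of 0.20 that differ in sign. p53 target genes had 3 higher (Zmat3, Pmaip1, Fas) and 2 lower (Rrm2b, Psrc1) of 21 (0.621), and BCL2 family genes 2 higher (Pmaip1, Bik) and 1 lower (Bak1) of 12 (0.7). Stress genes had 0 higher and 2 lower (Dnajb1, Hsph1) of 15 (0.222), and interferon response genes 0 higher and 1 lower (Rsad2) of 22 (0.744). Markers of cells outside the gate were few: myeloid genes had 0 higher and 1 lower (Itgam) of 4 (0.7), dendritic cell and macrophage genes 0 of 11 (0.744), erythroid and platelet genes 0 higher and 1 lower (Car2) of 7 (0.7), and stromal and epithelial genes 1 higher (Krt18) and 0 lower of 5 (0.222). Cytotoxic and mature effector genes had 0 of 7 (0.744), with a median log2 change of 0.08 and a mean of -0.11. Over the list alone these counts were the same except for PRC2 (2 lower), CDK inhibitors (3 higher, 2 lower), B lineage (5 lower), myeloid (1 higher, 2 lower) and interferon (0 lower). By fry, PRC1 subunits (adjusted p = 0.0439), p53 target genes (0.0439), BCL2 family genes (0.04995) and stromal genes (0.00259) passed in the higher direction. As fry does not compare a list with the other genes, these passes do not set the lists apart. The median log2 change of PRC1 subunits was 0.04. With the replicate block further members passed: Suz12 (0.0158), Phf19 (0.0319), Cdkn2d (0.0084) and Lyz2 (0.0195) lower, and Pcgf2 (0.0393), Oasl2 (0.0175), Usp18 (0.0223) and Bmf (0.0171) higher. Single libraries decided several of these calls. That of Rsad2 was lost without any of the 6 pro-B libraries (adjusted p of at most 0.147), and that of E130012A19Rik without any but DKO 2 (0.122). Without pro-B control 2 the calls of Rbbp7 (0.105), Rybp, Ring1, Cdkn2c, Rrm2b (0.0659), Bak1 (0.0671), Dnajb1 (0.0589), Hsph1 and Itgam were also lost. Control 1 further decided Rybp, Ring1 and Cdkn2c, control 3 Rbbp7, Ring1, Cdkn2c and Hsph1, DKO 2 Ring1, and each DKO library Itgam; the largest adjusted p was 0.0784 for Rybp, 0.0885 for Ring1, 0.146 for Cdkn2c, 0.0854 for Hsph1 and 0.0943 for Itgam. The stress list passed without pro-B DKO 1 (0.00922), but not with an estimated correlation there (0.565).

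Antigen receptor V segments were looked at after their values were seen. Of 69 heavy chain V segments tested in pro-B cells (chromosome 12, 113578504 to 116000461), 40 were lower in DKO and 1 was higher, and their summed reads were 219 ± 81.0 CPM in controls and 104 ± 43.7 CPM in DKO. The Ighv2 and Ighv5 families, which lie nearest to the D and J segments, had 0 of 15 lower and a median log2 change of 0.17. The other families had 40 of 54 lower and a median of -1.13; the distant Ighv1 and Ighv8 families fell from 119 ± 45.1 to 17.8 ± 10.7 CPM in sum over 34 segments. Segments of a family are near-identical, so the reads of single segments are uncertain.

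**Figure D2:**
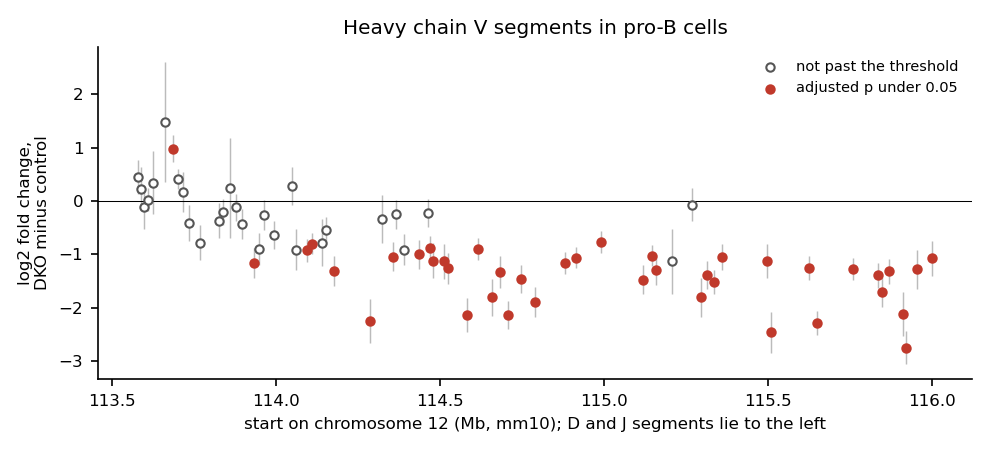
Log2 fold change, DKO minus control, of 69 heavy chain V segments in pro-B cells against their start on chromosome 12 (points with SE bars; filled points passed adjusted p 0.05). Segments near the D and J genes scatter around 0 (median 0.17 for Ighv2 and Ighv5) and most segments farther away lie below it (median -1.13).

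Without pro-B control 2 the pro-B counts dropped to 917 higher and 199 lower, without control 3 to 1214 and 378, without control 1 to 845 lower and without DKO 2 to 756 lower. Calls lower stood at 2367 with the replicate block and 686 with the ribosomal RNA covariate, and without scaling 77.1% of calls were higher, against 59.5%, when the median of all genes moved from -0.05 to 0.07 on the log2 scale.

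**Figure D3:**
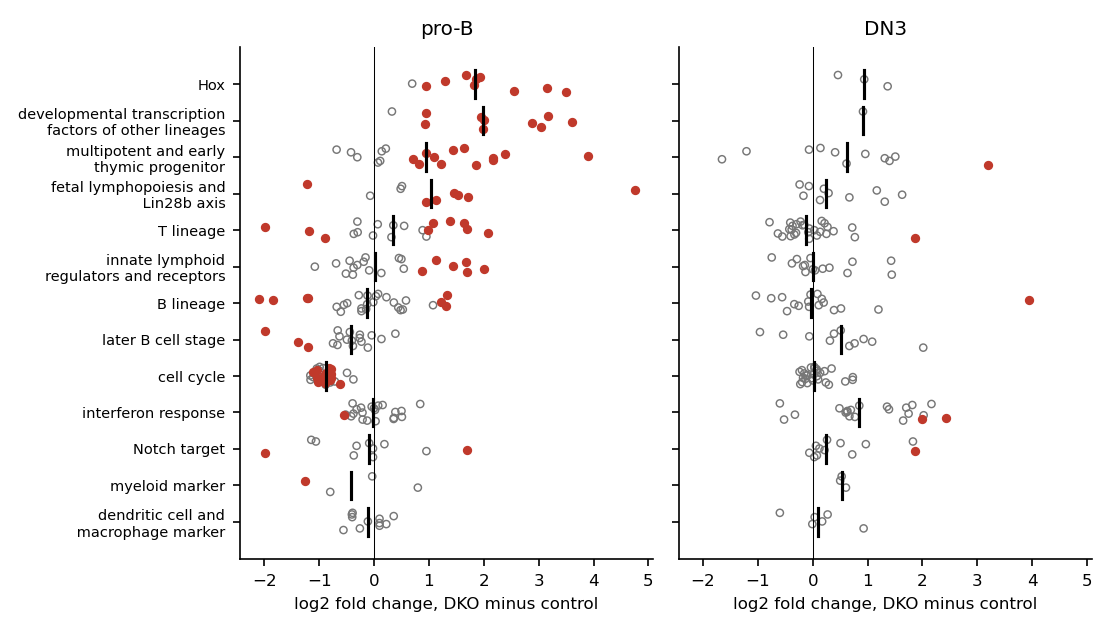
Log2 fold change, DKO minus control, of each tested member (points; filled where adjusted p was under 0.05) of 13 of the 24 lists in pro-B and DN3 cells, with the list median as a bar. In pro-B the Hox and developmental transcription factor medians lie at 1.85 and 1.99 and the cell cycle median at -0.88; in DN3 the cell cycle median lies at 0.02 and the interferon median at 0.85.

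How DN3 thymocytes of the DKO genotype differ from controls was addressed in the same way, with DN3 DKO libraries that held less ribosomal RNA (4.99 ± 1.91% of reads) than DN3 controls (14.4 ± 7.18%). Here too the largest changes were rises from near 0. Bmpr1a went from 0.0595 ± 0.0653 to 34.4 ± 9.48 CPM (log2 change 5.03 ± 0.44, adjusted p = 0.000783), the TALE homeodomain factor Pbx3 from 1.98 ± 1.38 to 48.6 ± 15.7 CPM (log2 change 4.13 ± 0.49) and the metalloprotease Adam19 from 0.278 ± 0.482 to 19.4 ± 1.81 CPM (log2 change 4.06 ± 0.46). Mpped2, Dmxl2, Scara3, Osbp2, Plekha8, Cecr2 and Ranbp17 rose by 4.35, 4.21, 4.17, 4.06, 3.97, 3.95 and 3.91 on the log2 scale. Of 14029 genes tested 272 rose and 15 fell, with median log2 changes of 2.45 and -1.25. Of those that rose 140 (51.5%) had under 1 CPM in controls, and of those that fell 2 had under 1 CPM in DKO, under the same filter. Mpped2 (adjusted p = 0.0522), Osbp2 (0.0747) and Ranbp17 (0.111) lost their calls with voom, and Ranbp17 also with pseudocount 0.1 (0.0523) and without DKO 1 (0.0671), DKO 2 (0.102) or DKO 3 (0.121). With the ribosomal RNA covariate all 10 lost theirs. Log2 changes for Ranbp17 were 3.91 before and 2.42 after; those of the other 9 stayed close, with 5.12 for Bmpr1a, 4.04 for Pbx3 and 4.32 for Adam19.

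Among the genes that fell in DN3 DKO, the T cell receptor gamma constant gene Tcrg-C1 went from 200 ± 16.1 to 101 ± 29.3 CPM (log2 change -1.02 ± 0.22, adjusted p = 0.0351) and the interferon gamma receptor gene Ifngr1 from 238 ± 42.8 to 105 ± 44.8 CPM (log2 change -1.24 ± 0.27, adjusted p = 0.0373). Sema4a fell from 69.0 ± 1.31 to 29.6 ± 0.482 CPM, and Tmem221, Hspa1b, Olfr524, Clec12a, Tcrg-C3, Gprin3 and Clec2d fell with log2 changes of -2.53, -2.38, -2.31, -2.24, -1.94, -1.56 and -1.33. Each of these 10 calls was lost when at least 1 single library was left out, and 0 calls lower stayed without DN3 DKO 2 or without DKO 3. Olfr524, Tcrg-C1 and Tcrg-C3 belong to families of near-identical genes, so their reads are uncertain. The ribosomal RNA share was 14.4% in controls and 4.99% in DKO for these genes too. With the ribosomal RNA covariate all 10 lost their calls. Log2 changes then shrank to -1.41 for Hspa1b, -1.30 for Clec12a and -0.78 for Clec2d. Those of the others moved less, with -1.37 for Tcrg-C1.

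Of the 22 lists large enough to test in DN3, the interferon response list alone passed by camera with the preset correlation. It had 2 higher and 0 lower of 21 (9 higher adjusted over the list alone; median log2 change 0.85, camera adjusted p = 4.16e-06), and the call was lost with an estimated correlation (adjusted p = 0.384; fry 0.0708). By fry 5 other lists passed in the higher direction: the fetal list (0.00693), Notch target genes (0.00693), p53 target genes (0.00971), PRC1 subunits (0.0317) and Hox genes (0.0317). Its called members were the antiviral enzyme Oas2, at 0.716 ± 0.856 and 8.33 ± 4.94 CPM, and Ifi44, at 2.43 ± 0.699 and 12.8 ± 3.50 CPM. Both calls were lost without any of the 3 DN3 DKO libraries or without control 3, Oas2 also without control 1 and Ifi44 without control 2. Both were lost with a sex term (0.0656 and 0.0713), voom (0.185 and 0.117), pseudocount 0.1 (0.0815 and 0.0580) and the ribosomal RNA covariate (0.486 and 0.592). The log2 changes of 2.44 and 2.0 were larger with the covariate, at 3.0 and 2.35. These libraries differ in ribosomal RNA as given above, 14.4% of reads in controls and 4.99% in DKO.

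Single members rose in other DN3 lists, between libraries with that same difference in ribosomal RNA share (14.4% and 4.99%). PRC1 subunits had 1 higher of 19 (camera adjusted p = 0.696), Bmi1, from 18.2 ± 9.13 to 66.9 ± 5.46 CPM. Notch target genes had 1 of 12 (0.08) and T lineage genes 1 of 28 (0.294), in both cases Dtx1, a regulator of Notch signalling, from 35.2 ± 17.5 to 121 ± 16.5 CPM. Progenitor genes had 1 of 11 (0.0849), Meis1, with 0 reads in controls and at least 147-fold higher in DKO against a floor of 3 reads over the group. p53 target genes had 2 of 21 (0.217), Pmaip1 and Zmat3, BCL2 family genes 1 of 12 (0.723), Pmaip1 again, and B lineage genes 1 of 17 (0.96), Cecr2. Stress genes had 1 lower of 16 (0.116), Hspa1b. The calls of Bmi1, Dtx1, Pmaip1 and Zmat3 were lost without any single DN3 DKO library, with adjusted p from 0.0609 to 0.253. Without controls 1 and 2, where the lone control 3 is assumed to vary like the DKO libraries, Bmi1 (0.0654), Pmaip1 (0.277) and Hspa1b (0.208) were lost. The log2 change of Bmi1 was 1.92, 1.21 in that fit and 1.3 with the ribosomal RNA covariate (0.823). Those of Pmaip1 and Zmat3 were also lost without control 2 (0.113 and 0.116) or control 3 (0.0537 and 0.109), and that of Meis1 without DKO 2 (0.0651) or DKO 3 (0.0710). With a sex term the calls of Zmat3 (0.0626) and Hspa1b (0.0641) were lost. The Notch list passed without DN3 control 1 (0.0301) and without scaling (0.0286). The stress list passed without control 2 (0.00014), without DKO 1 (0.0129) and without scaling (0.00905). With the ribosomal RNA covariate the progenitor list passed (0.000723). None of these passed in the same fits with an estimated correlation: 0.584 and 0.603 for Notch, 0.452, 0.649 and 0.669 for stress and 0.376 for progenitor genes.

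The other DN3 lists had 0 members past the threshold in the main fit, with ribosomal RNA at 14.4% of control and 4.99% of DKO reads here as well. Members that passed in alternatives include Hoxb3 (adjusted p = 0.0107), Plagl1 (0.0130), Irf4 (0.00958) and Cdkn2b (0.0348), all higher with all 12 libraries. Rora passed higher without control 1 (0.0180), and Pim1 lower with the replicate block (0.0319). By camera, adjusted p was 0.424 for PRC2 subunits and partners (11 tested), 0.981 for innate lymphoid regulators (15), 0.125 for the fetal list (10), 0.662 for CDK inhibitors (6), 0.0849 for Hox genes (3), 0.198 for later B cell stage genes (11) and 0.776 for post-beta-selection genes (14). It was 0.444 for myeloid (3), 0.981 for dendritic cell and macrophage (6), 0.982 for stromal and epithelial (5), 0.981 for cytotoxic effector (7), 0.981 for cell cycle (28) and 0.0849 for IL-7 receptor and STAT5 target genes (16). Erythroid and platelet genes (2 tested) and transcription factors of other lineages (1 tested) were too few for the test. Median and mean differed in sign for B lineage (-0.04 and 0.18), stromal (-0.12 and 0.12) and BCL2 family genes (-0.18 and 0.11). The camera direction was opposite to the median for B lineage, stromal, cell cycle and post-beta-selection genes. Without DN3 control 1 the cell cycle list passed in the lower direction (0.000134), as it did with the ribosomal RNA covariate (0.0285) and without controls 1 and 2 (1.62e-09, where the lone control 3 is assumed to vary like the DKO libraries), and the later B cell list passed (0.0391). The IL-7 receptor list passed without DKO 1 (0.0392) and the Hox list with the covariate (0.0298). With an estimated correlation none of these passed (0.665, 0.735 and 0.642 for cell cycle, 0.584 for later B cell, 0.411 for IL-7 receptor and 0.376 for Hox genes). Adjusted over the list alone, 2 PRC1, T lineage and Notch members were higher, 1 CDK inhibitor, Hox gene, transcription factor of other lineages, later B cell gene and erythroid gene, and 2 stress genes and 1 BCL2 family gene were lower; the remaining counts were the same.

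DN3 counts rest on single libraries: 48 genes were higher without DKO 3, 57 without DKO 2, 104 (6 lower) without DKO 1 and 168 (5 lower) without control 2, and 154 higher and 1 lower without controls 1 and 2, a fit in which the lone control 3 is assumed to vary like the 3 DKO libraries. With the ribosomal RNA share as a covariate limma called 0 genes, with 589 at an unadjusted p under 0.05. The voom fit, also run within limma, called 83 higher and 5 lower, and log2(RPKM + 1) gave 31 and 2. Without scaling it was 493 and 5, when the median of all genes moved from 0.01 to 0.30 on the log2 scale.

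**Figure D4:**
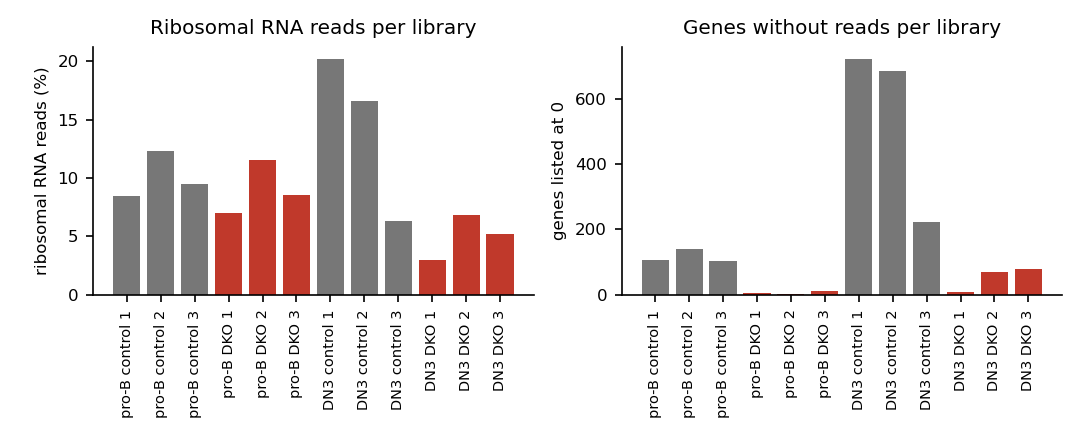
Share of reads from the ribosomal RNA locus (left) and number of listed genes without reads (right) in each library; grey bars are controls and red bars DKO. DN3 controls 1 and 2 hold 20.2% and 16.6% ribosomal RNA and 722 and 684 genes listed at 0, while DN3 control 3 lies at 6.36% and 222.

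Whether the genotype effect differed between the cell types was tested with the interaction over 13166 genes. In 37 genes the DKO effect was higher in DN3 and in 87 it was lower. Each gene had 1 residual spread over all 12 libraries in this fit, so its SE is the same in both cell types. Fitted alone, the median residual SD over genes was 0.229 in pro-B and 0.412 in DN3. Spats2 rose in pro-B DKO with a log2 change of 3.80 ± 0.25 against -0.10 ± 0.25 in DN3 (interaction -3.89 ± 0.35, adjusted p = 0.000173), and Zfhx3, Sestd1, Tead1 and Atp11a had interactions of -3.60, -2.87, -4.32 and -2.72. In the other direction, the chromatin remodelling factor Cecr2 had 0.28 ± 0.20 in pro-B and 3.92 ± 0.20 in DN3 (interaction 3.64 ± 0.29, adjusted p = 7.56e-05), and Adam19, H2-Q7, Cacna1e and Dscam had interactions of 4.30, 1.86, 3.14 and 3.47. Cecr2, Spats2 and Zfhx3 passed in every alternative. With voom Tead1 (-2.35, adjusted p = 0.564), Adam19 (0.0862), Cacna1e (0.169) and Dscam (0.0609) were lost, Tead1 also with pseudocount 0.1 (0.127) and Cacna1e with pseudocount 5 (0.0767). Without DN3 controls 1 and 2 Cacna1e (0.0822) and Dscam (0.0511) were lost. The ribosomal RNA covariate ended the calls of Adam19, H2-Q7, Cacna1e, Dscam, Sestd1, Tead1 and Atp11a (0.0647 to 0.307), while their sizes stayed close. These were 4.29, 1.68, 3.12, 4.06, -2.96, -4.36 and -2.87. Over all 124 calls the median size was 2.26 before and 1.97 after, the SE 0.411 and 0.546, and 124 kept their sign with an unadjusted p under 0.05. H2-Q7 is a class I gene with near-identical neighbours, so its reads are uncertain. Of the 2599 genes called in pro-B but not DN3, 88 had an interaction past the threshold, as had 17 of 50 called in DN3 but not pro-B, so most calls made in 1 cell type are not shown to differ between them. Without pro-B control 2, 7 and 31 genes passed, without pro-B control 3, 10 and 36, and without DN3 control 3, 108 and 137. It was 18 and 43 without pro-B DKO 1, 15 and 46 without pro-B DKO 3, 14 and 40 without DN3 DKO 2 and 18 and 44 without DN3 DKO 3. Genes with a higher effect in DN3 were 18 without pro-B control 1, 20 without pro-B DKO 2 and 24 without DN3 DKO 1. With the ribosomal RNA covariate 1 and 2 passed, with voom 16 and 39, and without DN3 controls 1 and 2, where the lone control 3 is assumed to vary like the other groups, 17 and 41.

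Calls were compared across the 13054 genes tested in both cell types. No library is shared between them, but in both the libraries numbered 3 were female by their reads. Whether the cell types came from the same animals is not stated, so the 2 comparisons may not be independent. Of 237 genes that rose in DN3 DKO, 194 (81.9%) also rose in pro-B DKO, where 1521 rose; 27.6 would be shared by independent lists (one-sided Fisher's exact test, p = 2.89e-141). They are 71.3% of all 272 genes that rose in DN3. A gene low in controls is in the other table mostly if it rises there too, which raises the share. Among 11949 genes with at least 1 CPM in the controls of both cell types, a check made after the overlap was seen, 77 of 99 (77.8%) were shared against 8.58 expected (one-sided Fisher's exact test, p = 1.02e-62). The shared genes include Bmpr1a, Mpped2, Pbx3, the Wnt receptors Fzd3 and Ryk, Chn1, Cep112, the Tead partner Yap1, Dmxl2 and Fam135a. Fzd3 went from 0.534 ± 0.152 to 19.8 ± 2.11 CPM in pro-B and from 0.136 ± 0.183 to 14.4 ± 2.74 CPM in DN3, and Yap1 from 1.15 ± 0.065 to 22.5 ± 11.5 CPM and from 2.88 ± 0.694 to 47.9 ± 18.5 CPM. Among genes that fell, 2 of 10 DN3 calls, Slc39a6 and the chemokine receptor Cxcr4, were also among 1230 pro-B calls, with 0.942 expected (one-sided Fisher's exact test, p = 0.242), and 2 genes were called in opposite directions. The overlap of genes that fell was 0 without pro-B control 2, DN3 control 2 or any DN3 DKO library, and 1 without pro-B control 3, pro-B DKO 1 or DN3 control 3. Log2 changes correlated across genes at r = 0.481 and rho = 0.344, though genes are not independent replicates. Of pro-B genes that rose, 78.8% had a positive log2 change in DN3 (50.1% of all genes), with a median of 0.56 against 1.11 in pro-B. The overlap of genes higher fell to 39 without DN3 DKO 3, 47 without DKO 2, 84 without DKO 1, 123 without DN3 control 2 and 0 with the ribosomal RNA covariate, since no DN3 gene was then called; it was 61 with voom, 121 without DN3 controls 1 and 2 and 313 without scaling.

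**Figure D5:**
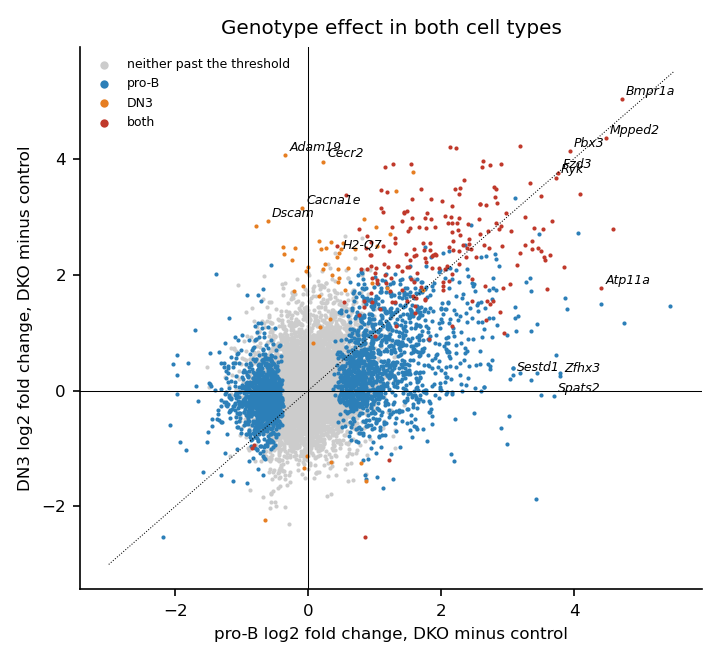
Log2 fold change, DKO minus control, of 13054 genes in pro-B (x axis) and DN3 (y axis), coloured by the cell type in which adjusted p was under 0.05; the dotted line marks equal change. Genes called in both lie mostly in the upper right (194 higher in both), and the labelled genes named for the interaction lie away from the dotted line (Tead1 is not drawn, as it was under the filter in DN3 alone).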

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

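The tests of other cell types, of ribosomal RNA reads in pro-B and of genes overlapping Cdkn2a, and every fit with the ribosomal RNA covariate or without DN3 controls 1 and 2, were chosen only after the results were seen.

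The genotype effect differed between pro-B and DN3 cells by the interaction test in 37 genes with a higher DKO effect in DN3 and 87 with a lower one. For the genes named by rule the interaction log2 values (DN3 minus pro-B) were 3.64 for Cecr2, 4.30 for Adam19, 1.86 for H2-Q7, 3.14 for Cacna1e, 3.47 for Dscam, -3.89 for Spats2, -3.60 for Zfhx3, -2.87 for Sestd1, -4.32 for Tead1 and -2.72 for Atp11a. Tead1 (adjusted p = 0.564), Adam19 (0.0862), Cacna1e (0.169) and Dscam (0.0609) were lost with voom, and all but Cecr2, Spats2 and Zfhx3 with the ribosomal RNA covariate. With it the 124 calls kept their sign, with a median size of 2.26 before and 1.97 after and an SE of 0.411 and 0.546. Of the genes named elsewhere, 14 also passed: -4.09 for Ptprm, -3.70 for Lin28b, 1.45 for Tspan2, 2.57 for Als2cl, -1.67 for Ikzf2, 3.32 for Irf4, -2.0 for Gata3, 2.83 for Heyl, -2.28 for Kit, 2.67 for Rsad2, -3.41 for Tmem221, -2.48 for Gprin3, -1.64 for Ifngr1 and -2.46 for Sema4a. Of 22 lists tested, 7 differed by camera: the fetal list (adjusted p = 0.0248), stromal and epithelial genes (0.0441) and IL-7 receptor and STAT5 target genes (0.00383) had a lower effect in DN3. Later B cell stage genes (0.000508), Notch target genes (0.0416), cell cycle genes (3.72e-07) and interferon response genes (7.72e-06) had a higher effect there. With an estimated correlation 0 of the 22 lists passed (smallest adjusted p = 0.212), and 7 had passed with the preset correlation. The list test was repeated in each alternative but voom after this was seen. The median cell cycle interaction of 0.85 became 0.49 without DN3 control 1 (0.00259; 0.521 with an estimated correlation), 0.38 with the ribosomal RNA covariate (0.0428; 0.653) and 0.18 without DN3 controls 1 and 2 (0.152; 0.730), where the lone control 3 is assumed to vary like the other groups. In that last fit only later B cell stage and interferon response genes passed of the 7. With the covariate the fetal (0.0555), IL-7 receptor (0.0555), Notch (0.108) and stromal (0.174) lists lost their calls, and with the replicate block the stromal list did (0.0774). The fetal, stromal and Notch lists also lost theirs without some single libraries (at most 0.0647, 0.0980 and 0.111), while progenitor genes passed in 8 alternatives (smallest adjusted p = 0.0106, without scaling). With an estimated correlation only later B cell stage genes without pro-B control 1 passed in any alternative (0.0228).

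Whether chance can be excluded for the interaction count is not settled by drawn labellings. Of 100, the real one included, 6 gave at least the real 124 calls, and the highest other gave 244. The 5 others all kept the real pro-B split, so a difference between the cell types was built into them; of 90 labellings without it the highest gave 11, but these also mix the genotypes within groups. Neither kind shows what equal effects in both cell types would give, and the high counts point to the pro-B genotype effect as a structure of the samples.

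The first pattern weighed is the rise of 724 pro-B genes from under 1 CPM in controls. The tables list such genes mostly through DKO, as they keep genes over 1 CPM in at least 2 libraries, but the filter treats the genotypes alike and 76 genes fell to under 1 CPM in DKO. Differentiated myeloid, dendritic or erythroid cells in the DKO sorts are argued against by their markers. With the stromal list added, 3.70% of the 27 tested members of 4 lists (76 listed, 49 under the filter) were higher in DKO. Their sum was 815 ± 269 CPM in controls and 704 ± 93.2 CPM in DKO. The myeloid, dendritic and erythroid lists went from 39.7 to 20.1, from 510 to 382 and from 74.4 to 56.9 CPM. The stromal and epithelial list went the other way, from 191 to 245 CPM. Of its 5 tested members 1, Krt18, was called higher. The list passed by fry (adjusted p = 0.00259), which does not compare it with the other genes, but not by camera (0.222). Stromal cells therefore stay open. Of the 27 members 3 are also in lymphoid lists and 9 exceeded 10 CPM in controls. The CD19+ B220+ CD43+ gate is set to exclude such cells. Members were called higher among progenitor genes (12 of 19, 0 lower), T lineage genes (6 of 19, 3 lower) and innate lymphoid regulators (6 of 20, 0 lower). By camera the progenitor list passed (adjusted p = 7.17e-05, 0.117 with an estimated correlation). The T lineage (0.222) and innate lymphoid (0.258) lists did not. A changed share of progenitors or of other lymphoid cells stays open. The gate is set to exclude those cells as well, but the purity of the sorts was not measured here. Ribosomal RNA as the whole cause is argued against by the covariate, which left 80.2% of these genes called, at a median log2 change of 1.31 before and 1.31 after. The 10 splits of 6 libraries are too few for a share under 0.05 (real 3317 calls, highest other 0); loss of PRC2 silencing stays a hypothesis, which these data may reflect but which no chromatin measurement here tests.

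The second pattern is the rise of genes in DN3 DKO, whose controls held more ribosomal RNA. DN3 control 3, at 6.36% ribosomal RNA, was held out, and the genes called without it sat in it at a median position of 0.225 between controls 1 and 2 (0) and DKO (1), quartiles 0.0223 and 0.435; the held-out DKO 2, at 6.80%, sat at 0.965. This argues against ribosomal RNA as the whole cause, but the shift of control 3 toward DKO leaves a part open. The covariate ended all 272 calls; the share goes with genotype and the term costs a degree of freedom, and a part played by ribosomal RNA was not told apart from that. The median log2 change was 2.45 before and 2.36 after, the SE 0.451 and 0.718, with 4 and 3 residual degrees of freedom, 100% kept their sign and 254 had an unadjusted p under 0.05. For the interaction, 100% of the 124 calls kept their sign and at least 50% of their size without DN3 controls 1 and 2, which leaves control 3 alone. These genes were picked in a fit that shares its other libraries with this one. That outcome was therefore likely in advance and does not decide on ribosomal RNA. The 10 splits in DN3 are too few for a share under 0.05 (real 287, highest other 0).

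The third pattern is that Cdkn2a reads were higher in DKO although both genotypes are Cdkn2a-/-. A mislabelled library is argued against, as 0 of 12 held-out libraries lay nearer to the other genotype's mean. Reads of an overlapping annotated gene are argued against, as 0 other genes overlap its span and Cdkn2b lies 11645 bp away. A transcript that remains at the deleted locus, and may rise with the loss of PRC2 like Cdkn2b next to it, and an allele left intact stay open: the labels do not name the deleted exons, and reads per exon were not analysed here.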

How the results depend on the processing

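Added after the data were seen were no scaling, voom, log2(RPKM + 1), the ribosomal RNA covariate, the sex term and the fit without DN3 controls 1 and 2; the DESeq2 Wald and edgeR exact alternatives were not run, as the deposited unit is RPKM. No call past the threshold changed direction under any alternative. Among named genes, which were not followed on log2(RPKM + 1), signs changed only where neither fit passed. Examples are Jarid2 (-1.50) and Cd44 (-1.65) in DN3, which reached 0.54 and 0.67.

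Pro-B counts of 1975 higher and 1342 lower became 2367 lower with the replicate block, 913 and 177 with all 12 libraries, 652 lower without scaling, 1237 higher on log2(RPKM + 1), 686 lower with the ribosomal RNA covariate and 1207 and 193 with the bound of 1 on the log2 change. DN3 counts of 272 and 15 became 572 and 91 with all 12 libraries, 493 and 5 without scaling, 83 and 5 with voom, 31 and 2 on log2(RPKM + 1), 0 and 0 with the covariate (limma, 589 at an unadjusted p under 0.05), and 154 and 1 without controls 1 and 2, where the lone control 3 is assumed to vary like the DKO libraries. Lower calls in DN3 were 9 with pseudocount 0.1 and 30 with the replicate block (292 higher), where same-number correlations were 0.162, 0.0417 and 0.164 and the Notch list passed by camera (0.0498; 0.568 with an estimated correlation), while Oas2 (0.0527), Ifi44 (0.0583) and Tcrg-C3 (0.0571) lost their calls.

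Interaction counts of 37 and 87 became 39 lower without scaling, 16 and 39 with voom, 1 and 2 with the covariate, and 17 and 41 without DN3 controls 1 and 2. The overlap of 194 higher became 313 without scaling, 61 with voom, 0 with the covariate and 121 without DN3 controls 1 and 2. The overlap of 2 lower became 6 with the replicate block, 1 with either pseudocount, voom or the sex term, and 0 without scaling, with the covariate, without DN3 controls 1 and 2 and with the bound on the log2 change. The bound removes genes by construction and leaving out controls removes samples; for the other settings the cause was not tested.

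Leaving out 1 library gave 917 to 1894 pro-B genes higher (lowest without control 2, highest without DKO 3) and 199 to 1102 lower (the same libraries). It gave 48 to 292 DN3 genes higher (without DKO 3, without control 1) and 0 to 22 lower (without DKO 2, without control 3), an interaction of 7 to 108 higher and 31 to 137 lower (without pro-B control 2, without DN3 control 3), and an overlap of 39 to 214 higher (without DN3 DKO 3, without DN3 control 1) and 0 to 2 lower.

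Named pro-B genes kept their side of the threshold in 1661 of 1770 comparisons, were lost in 75 and gained in 34; in DN3 it was 1543 of 1752, with 172 lost and 37 gained. Lists kept theirs in 301 of 312 in pro-B and 293 of 307 in DN3, and named interaction genes in 205 of 220. Named genes were not followed on log2(RPKM + 1), so these tallies leave that fit out. It gave 1237 higher and 1026 lower in pro-B and 31 and 2 in DN3. In the alternatives that were followed the 10 largest pro-B rises always passed, as did 8 of the 10 largest falls. Of the 10 largest DN3 rises 7 were lost there with the covariate alone. Depth limits genes near the floor of 0.115 to 0.211 CPM per library.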

Other observations

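The tests of heavy chain segments were chosen only after the values were seen, as were the gamma locus genes; the test of neighbouring genes was written before its result.

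In DN3 DKO, 3 of 9 genes tested at the T cell receptor gamma locus on chromosome 13 were lower: Tcrg-C1, Tcrg-C3 and Trgv2. Trgv2 went from 77.0 ± 12.9 to 36.7 ± 5.86 CPM (limma, adjusted p = 0.0427), Tcrg-C2 missed the threshold (log2 change -0.93, 0.0510), and Tcrg-C4 (-0.24, 0.691), Tcrg-V4 (-0.45, 0.717), Tcrg-V7 (-0.09, 0.965), Trgj1 (0.636) and Trgj2 (0.325) did not pass. The calls of Tcrg-C1 (0.0515) and Tcrg-C3 (0.0528) were lost with a sex term, that of Tcrg-C3 without any of the 6 DN3 libraries (0.0597 to 0.193) and that of Tcrg-C1 without 4 of them (at most 0.197). The locus was not tested as a set. Tcrg-C1, Tcrg-C2 and Tcrg-C3 are close copies of each other, and ribosomal RNA was 14.4% of control and 4.99% of DKO reads.

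A hypothesis is that V segments of the heavy chain locus drop more in pro-B DKO with distance from the D and J segments. Across 69 segments position and log2 change had a Spearman rho of -0.769 (permutation p = 1e-05, the smallest these permutations can give); segments are not independent replicates. An even drop of all segments is argued against by a median difference of 1.3 between the Ighv2 and Ighv5 families and the others (permutation p = 1e-05, again the smallest). Whether fewer rearranged cells would lose all segments evenly was not tested, so fewer rearranged cells stay open. A change in locus folding or in the use of distant segments may also underlie the uneven drop, and none of these was measured here. Pax5 (log2 change 0.58, adjusted p = 0.0635), Ighm (-0.49, 0.175), Yy1 (-0.26, 0.129) and Ctcf (-0.35, 0.116) did not pass.

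A further hypothesis is that neighbouring genes rise together in pro-B DKO, as Lin28b and Bves next to it do. Among neighbours over 10 kb apart, both genes were higher in 298 cases against a permutation mean of 149 (126 to 171), a ratio of 2.01 (permutation p = 1e-04, the smallest these permutations can give). For genes lower the count was 48 against 61.7 (permutation p = 0.975). Over all neighbours that do not overlap it was 384 against 230 for genes higher (permutation p = 1e-04) and 130 against 97.9 for genes lower (permutation p = 0.0003), so close neighbours fall together too. In DN3 genes higher over 10 kb apart gave 4 against 2.78 (permutation p = 0.302), and over all neighbours 8 against 4.26 (permutation p = 0.0688). For the 14 genes lower in DN3 a lone pair was found, against 0.0138 over all neighbours and 0.0097 over 10 kb apart (permutation p = 0.0139 and 0.0098). Tcrg-C1 and Tcrg-C3, close copies with uncertain reads, were both lower at the gamma locus and may be this pair, so it carries little weight. Silenced domains that span several genes may explain the neighbouring rises in pro-B DKO. Shared regulation or reads running on from a neighbour were not told apart from such domains.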
